A study of Mus musculus with 9 samples.

How the data were processed

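RNA from LSK cells of 9 sorted samples, 3 each from control mice, from GFP-negative and from GFP-positive cells of dnMPL mice, was amplified, labelled with biotin and hybridised to mouse Affymetrix arrays, 1 array per sample. Each sample pooled marrow of 2 to 5 mice. Arrays of a group were taken as replicates because the labels list them as separate samples. The deposited log2 values are RMA values, per the submitters' processing notes, which name RMA without a version. RMA corrects background, quantile-normalizes arrays and summarises the probes of a probe set by median polish. Median polish can give several arrays the same value, and 19019 of 45101 probe sets had the same value on 2 or more arrays. All arrays of a group shared 1 value in 197 (control), 216 (GFP-negative) and 153 (GFP-positive) probe sets, against a mean of 190.02 over all 84 sets of 3 arrays, so the ties do not follow the groups, but they make the spread of such a probe set look too small. Scanner files were not used here.

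Of 45101 probe sets 64 were control probe sets. The platform annotation named 1 gene for 34945 of the others, several for 932 and none for 9160, and 34754 of those with 1 gene were matched to a RefSeq gene table by Entrez number. Probe sets with several genes were not named. Each gene was represented by its probe set with the highest mean over all arrays, and 12398 of 18193 genes had a mean above the 40th percentile of the probe sets (4.03) and were tested. Slamf1, Cdkn1c and Vwf fell below that filter, and only their levels are given. No genome build is given in the sources used here, and no coordinates are printed.

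Group means were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 9 arrays, so that the 3 groups shared 1 estimate of the spread, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1. The tests, the samples in them, the lists and most of the other settings tried were fixed before the data were examined. Results for 1 gene and 1 list are not reported here. The 31 lists hold 728 members, 69 of which matched no named probe set. They cover stem and progenitor cells (HSC identity, the study's Tek, Esam and Procr, multipotent and lymphoid-primed progenitors, myeloid priming, megakaryocytes and platelets), cell cycle (quiescence, G2/M and mitosis, G1/S and DNA replication, D-type cyclins and G1 regulators) and signalling (JAK-STAT target genes, interferon response, TNF and NF-kB response). Lists for metabolism and stress were ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, p53 targets, DNA repair, immediate early and heat shock, unfolded protein response, and adhesion and homing. Lists for other cells the gate could hold were erythroid, granulocyte, monocyte and macrophage, dendritic cell and MHC class II, B cell, T and NK cell, mast cell and basophil, and endothelial and stromal.

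Genes were named by a fixed rule: those past the threshold with groups that did not overlap; where fewer than 10 qualified, the 10 with the smallest p; the 4 members with the smallest p of each list that passed; and a fixed set that includes Tek, Esam, Procr, Slamf1, Flt3, Cdkn1c, Mki67 and Vwf. Hba-a1, Itga2b, Itgal, Pecam1, Mpo, Prtn3, S100a9 and list members named in a comparison for which the rule did not take them (such as Prdm16 and Mycn between the dnMPL fractions) were chosen after their values were seen. Alternatives changed the filter, the choice of probe set, the variance prior, array weights, the normalization, the threshold, the arrays in the fit, the replicate number as a block and the list test (estimated correlation, and fry from limma with statmod 1.5.0). The normalization alternatives chose each gene's brightest probe set anew, so a gene's value there can come from another probe set. Each array was left out in turn, and, chosen after the data were seen, control 3 and GFP-positive 2 were left out together and both dnMPL fractions were compared jointly with control.

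The methods were tested on simulated data for the same 12398 genes, with 50 genes changed at each size. Changes of 2 on the log2 scale were recovered for 44% of genes in GFP-positive against control, 58% in GFP-negative against control and 60% in GFP-positive against GFP-negative, and changes of 3 for 88%, 92% and 78%. Of 3 lists shifted by 0.7, camera called 3 in each comparison, and it called 1, 0 and 0 of the lists left unshifted. The simulated genes varied independently of each other, whereas the estimated correlation on the real arrays was 0.39 for granulocyte and 0.44 for oxidative phosphorylation genes. These counts therefore do not give the share of false list calls on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.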

Results

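Gene expression was measured in Lin-Sca1+cKit+ (LSK) cells, the bone marrow fraction that holds hematopoietic stem cells (HSCs) and multipotent progenitors, sorted from transplanted C57BL/6 mice 8 weeks after transplantation. The transgene, named dnMPL in the labels, was carried into donor cells by a retroviral vector, and GFP marked the cells that expressed it. Of the 3 groups, 1 held LSK cells of control mice that had received wild-type LSK cells, and the others held the GFP-negative and the GFP-positive LSK cells of mice given dnMPL-transduced cells. Each group had 3 arrays, and each array held RNA from the pooled marrow of 2 to 5 mice. The number of arrays limits the precision of every value. The labels do not say whether GFP-negative and GFP-positive samples of the same number came from the same mice, nor which vector, if any, the control cells carried, so effects of transduction and culture cannot be separated from those of dnMPL. Levels are log2 RMA values, and differences are log2 fold changes with a standard error (SE) from limma. Where both dnMPL fractions are set jointly against the controls, the SE comes from the pooled variance of the arrays, without limma. Array medians lay between 4.52 and 4.64, and correlations between arrays between 0.886 and 0.97. Control 3 and GFP-positive 2 stood apart from their groups, with array weights of 0.364 and 0.369 against 0.809 to 2.38 on the other 7 arrays. The gap between the 3′ and 5′ control probe sets of Gapdh, which widens when transcripts are incomplete, was 3.87 and 3.22 on these 2 and 2.47 to 2.89 on the others, and the 5′ level was 8.69 on control 3 against 9.71 to 10.2. Several list calls against control, G2/M and oxidative phosphorylation among them, ended without control 3.

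The first comparison asked what differed between LSK cells that carried dnMPL and LSK cells of control mice. In GFP-positive cells the HSC identity genes were lower and genes of granulocytes, erythroid cells and myeloid priming were higher. The median member of the HSC identity list, which holds transcription factors and surface proteins of stem cells, fell by 0.87 on the log2 scale, and 22 of its 24 measured genes were lower (camera adjusted p = 2.23e-10; adjusted p = 0.058 with an estimated correlation). Mycn, a MYC family transcription factor, differed by -3.24 ± 0.79 (SE) and Prdm16, a transcriptional regulator needed for stem cell maintenance, by -2.22 ± 0.49. These were the 2 genes of the list that fell with p adjusted over the list alone (0.0291 and 0.0291), and 0 fell over all genes tested. Angpt1, which encodes the angiopoietin ligand of Tek, and Ctnnal1 differed by -1.04 ± 0.32 and -1.17 ± 0.38 and did not pass (limma adjusted p = 0.0739 and 0.0739, adjusted over the list alone). With the mean of a gene's probe sets in place of the brightest, Mycn and Prdm16 differed by -1.04 and -0.88, and after a further quantile normalization Mycn differed by -0.21. The latter setting chose each gene's brightest probe set anew, so its value may come from another Mycn probe set, which was not checked.

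The granulocyte list rose by a median of 2.76 on the log2 scale, with 16 of 16 genes higher (camera adjusted p = 1.53e-16; adjusted p = 0.0942 with an estimated correlation). Adjusted over the list alone, 12 of its genes rose and 4 did not pass, and 0 rose over all genes tested. Ctsg and Elane, serine proteases of primary granules, rose by 2.61 ± 0.49 and 2.42 ± 0.62, and Lcn2 and S100a8, which are expressed later in granulocyte maturation, by 3.90 ± 1.09 and 3.38 ± 0.99. The late genes were not low in every control. S100a8 stood at 11.9 on control 3 against 9.04 and 7.43 on the other controls, and at 12.4 to 13.5 on the GFP-positive arrays. Ctsg, in contrast, was at 6.89 on control 3, below 8.84 and 8.58 on controls 1 and 2. The LSK gate takes cells without lineage markers. The antibodies named for the isolation of donor cells included GR1 and CD11b, which mark granulocytes and other myeloid cells. The myeloid priming list rose by a median of 0.66 (16 of 18 higher; camera adjusted p = 8.41e-10; adjusted p = 0.058 with an estimated correlation). It shares 4 genes with the granulocyte list. Adjusted over the list alone, 5 of its genes rose, among them Fcgr3, an Fc gamma receptor, by 1.92 ± 0.27 and Ms4a3, a marker of granulocyte-monocyte progenitors, by 2.56 ± 0.51, and 0 rose over all genes tested.

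The erythroid list rose by a median of 1.10 with 10 of 14 genes higher (camera adjusted p = 5.12e-07), and it was the 1 list of 31 that passed with an estimated correlation (adjusted p = 0.0377). Its estimate was negative (-0.0575), which camera counts as 0, so it was tested with a correlation below the preset 0.01. Adjusted over the list alone, 6 of its genes rose and 8 did not pass, and 0 rose over all genes tested. Slc4a1, the anion exchanger of the red cell membrane, rose by 4.36 ± 0.73 (2.35 by the mean of its probe sets), the carbonic anhydrase Car1 by 2.73 ± 0.49, the transferrin receptor Tfrc by 1.67 ± 0.38 and Ermap by 2.98 ± 0.66. Hba-a1, an alpha globin gene, was at 4.31 ± 0.39 in GFP-positive cells and 4.19 ± 0.25 in controls (SD, n = 3 each). Without GFP-positive 2 the list's median was 0.66, and without both arrays that stood apart it was 0.45 (camera adjusted p = 8.42e-06). Immediate early and heat shock genes, which cells switch on within minutes of a stimulus or stress, fell, with a median log2 fold change of -0.57 (19 of 21 lower; camera adjusted p = 5.12e-07; adjusted p = 0.193 with an estimated correlation). Egr1, Klf6, Nr4a1 and Jun, all transcription factors, differed by -1.92, -1.47, -2.11 and -1.10 and were the 4 genes that fell when adjusted over the list alone, with 0 over all genes tested. Klf6 differed by -0.57 by the mean of its probe sets. Mast cell and basophil genes rose by a median of 0.96 (0.62 without GFP-positive 1), with 8 of 10 higher and 0 past the list-alone threshold (camera adjusted p = 0.000335; adjusted p = 0.208 with an estimated correlation). The proteases Cma1 and Mcpt8 differed by 1.72 ± 0.53 and 1.21 ± 0.40.

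In 9 other lists camera passed, but leaving out single arrays ended the call. The study's own genes Tek, Esam and Procr, markers of stem cells chosen on these samples and so not independent evidence, fell, with a median log2 fold change of -1.503 (camera adjusted p = 0.0072; adjusted p = 0.193 with an estimated correlation). Procr, the endothelial protein C receptor, fell (-1.503 ± 0.37) when adjusted over the list alone (limma adjusted p = 0.0081). Tek and Esam differed by -1.76 ± 1.05 (-2.85 without GFP-positive 2 and -0.73 without GFP-positive 1) and -0.43 ± 0.37 and did not pass. The call ended without control 3 or GFP-positive 3 (adjusted p = 0.0796 and 0.0715), and without GFP-positive 1 the median was -0.73. G2/M and mitosis genes rose by a median of 0.37, with 24 of 29 higher (camera adjusted p = 0.000104; adjusted p = 0.316 with an estimated correlation). This call ended without control 3 (adjusted p = 0.0983), and the median lay between 0.15 and 0.69 without 1 array. Ccna2, cyclin A, and the mitotic kinase Plk1 differed by 0.90 ± 0.30 and 1.06 ± 0.39 (0.68 and 0.70 without control 3, and Ccna2 by 0.57 without GFP-positive 2 as well), and Mki67, a marker of cycling cells, by -0.013 ± 0.25. B cell genes rose by a median of 0.81 (12 of 13 higher; camera adjusted p = 0.000268; adjusted p = 0.208 with an estimated correlation), but not without control 2 (adjusted p = 0.0673, median 0.38). Pax5, the B cell transcription factor, stood at 7.6 and 9.45 on GFP-positive arrays 1 and 2 and at 4.89 on array 3. Monocyte and macrophage genes rose by 1.22 (9 of 13 higher; camera adjusted p = 0.00197; adjusted p = 0.234 with an estimated correlation), but not without GFP-positive 1 (adjusted p = 0.0762, median 0.55). Ccr2, a chemokine receptor of monocytes, rose by 1.94 ± 0.42 when adjusted over the list alone (1.25 by the mean of its probe sets).

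Genes of multipotent and lymphoid-primed progenitors rose by a median of 0.45 (16 of 23 higher; camera adjusted p = 0.00639; adjusted p = 0.188 with an estimated correlation), but not without control 2 or GFP-positive 3 (adjusted p = 0.0721 and 0.0868, the second with a median of 0.19), and the median was 0.17 without control 3. Rag1, the recombinase of lymphoid cells, differed by 2.17 ± 0.55, while the receptor kinase Flt3 differed by 0.059 ± 0.27. Tyrobp, Ctss and Irf8, with Rag1 the 4 members with the smallest p, were also higher. Irf8 is in the myeloid priming list as well, so the rises of these lists are not separate results. Oxidative phosphorylation genes rose by 0.28 (27 of 38 higher; camera adjusted p = 0.00318; adjusted p = 0.575 with an estimated correlation). That call ended without control 3 or GFP-positive 3 (adjusted p = 0.752 and 0.179), with medians of -0.049 and 0.10, and without control 2 the median was 0.43. Megakaryocyte and platelet genes fell, with a median log2 fold change of -0.37 (12 of 18 lower; camera adjusted p = 0.0339; adjusted p = 0.188 with an estimated correlation), but not without control 2, GFP-positive 1 or GFP-positive 3 (adjusted p = 0.147, 0.0762 and 0.102). Gng11 fell by 1.35 ± 0.32 when adjusted over the list alone, and Pf4, platelet factor 4, and Itga2b, an integrin of platelets, differed by -1.99 ± 0.78 (-1.17 without GFP-positive 2) and -0.66 ± 0.28 and did not pass. The unfolded protein response list rose by 0.22 (14 of 19 higher; camera adjusted p = 0.0317; adjusted p = 0.188 with an estimated correlation), with Pdia4, a protein disulfide isomerase, at 0.76 ± 0.29 (0.34 by the mean of its probe sets). It did not pass without control 2, control 3, GFP-positive 1 or GFP-positive 3 (adjusted p = 0.0673, 0.112, 0.105 and 0.176), and its median ranged from 0.056 to 0.38. Dnajb9, also among its 4 genes with the smallest p, went the other way. It stood at 7.09 to 7.80 on GFP-positive arrays and at 7.54 to 8.67 on controls. The dendritic cell and MHC class II list rose by 0.18 (8 of 12 higher; camera adjusted p = 0.0339; adjusted p = 0.234 with an estimated correlation), and its integrin gene Itgax rose by 1.99 ± 0.48 when adjusted over the list alone. This list did not pass without control 3, GFP-positive 1 or GFP-positive 2 (adjusted p = 0.113, 0.0536 and 0.14), and its median ranged from 0.10 to 0.38.

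The other 16 lists did not pass (camera adjusted p from 0.0966 to 0.681). Among those reported here, medians were 0.30 for endothelial and stromal genes, where Fabp4 rose when adjusted over the list alone (by 1.21 by the mean of its probe sets), -0.12 for TNF and NF-kB response, where Tnfaip3 fell, 0.083 for G1/S and DNA replication, 0.20 for D-type cyclins and G1 regulators and 0.11 for T and NK cells. JAK-STAT target genes had a median of -0.036, quiescence, where Egr1 and Nr4a1 fell when adjusted over the list alone, -0.0023, interferon response -0.18 and p53 targets 0.16. Ribosome biogenesis stood at 0.10, ribosomal proteins at -0.066, cholesterol synthesis at 0.21, DNA repair at -0.012, adhesion and homing at 0.024, and glycolysis and hypoxia at 0.049. The glycolysis and the adhesion lists had mean differences of the opposite sign to their medians (-0.00976 and -0.00498). Among single genes, 0 of 12398 passed limma at an adjusted p under 0.05 (smallest 0.228), 805 had an unadjusted p under 0.05 (409 higher, 396 lower) and 620 would by chance. In 1068 genes (8.61%) the groups did not overlap, against 10% by chance. The 10 genes with the smallest p, none of which passed, included Fcgr3 at 7.41 ± 0.30 in GFP-positive cells and 5.50 ± 0.30 in controls (SD, n = 3 each), the guanine deaminase Gda at 3.83 ± 0.59 (2.54 by the mean of its probe sets), the small GTPase Rala at 1.85 ± 0.28 (0.39 by that mean), and Dram1 and the fatty acid binding protein Fabp4 at 2.72 ± 0.44 and 3.02 ± 0.50. Lower by point estimate were the cytokine Il15 at -2.21 ± 0.34, Cadps2 at -2.95 ± 0.47, Fndc10 at -2.58 ± 0.42 (-1.63 after a further quantile normalization) and Zfr2 at -2.01 ± 0.34.

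**Figure D1:**
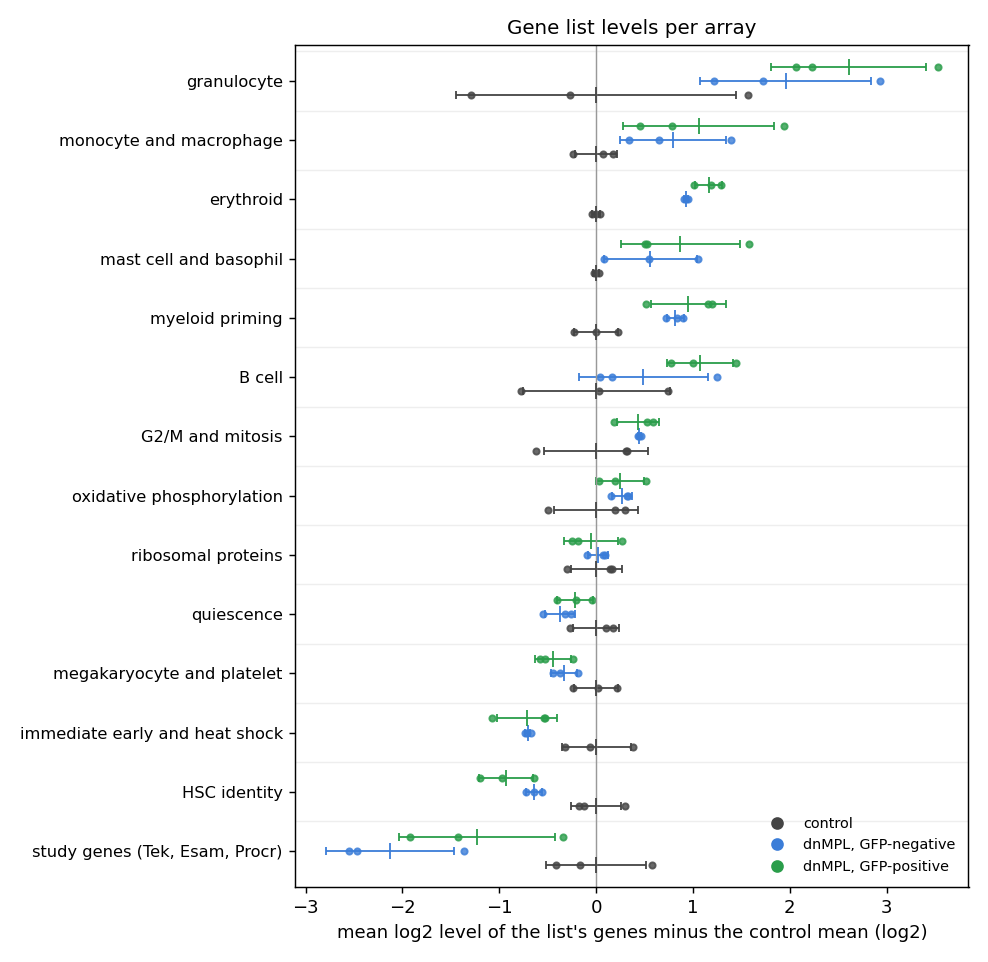
Mean log2 level of the genes of 14 lists on each array, minus the mean of the 3 control arrays (x axis, log2), for control, GFP-negative and GFP-positive LSK cells. Points are arrays and bars the mean ± SD (n = 3); the erythroid genes of all 6 dnMPL arrays lay between 0.91 and 1.29, above the controls, and the granulocyte level of control 3 was 1.56.

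The second comparison set GFP-negative LSK cells of the dnMPL mice, sorted as lacking the GFP marker, against the controls. HSC identity genes were again lower, and granulocyte, myeloid and erythroid genes higher. The HSC identity list fell, with a median log2 fold change of -0.53 (22 of 24 lower; camera adjusted p = 5.79e-06; adjusted p = 0.154 with an estimated correlation), with 0 genes past the list-alone threshold. Angpt1 differed by -0.92 ± 0.32, Prdm16 by -1.24 ± 0.49, Mycn by -1.84 ± 0.79 and the endothelial and stem cell gene Myct1 by -1.68 ± 0.70. Mycn differed by -0.067 after a further quantile normalization, Prdm16 by -0.62 by the mean of its probe sets and -0.80 without GFP-negative 2, and Myct1 by -0.93 without GFP-negative 3. That Mycn value, too, may come from another probe set. The granulocyte list rose by a median of 2.14 (16 of 16 higher; camera adjusted p = 2.27e-11; adjusted p = 0.162 with an estimated correlation), and without control 2, the control with the lowest granulocyte level, by 1.25. Adjusted over the list alone, Ctsg and Elane rose by 2.46 ± 0.49 and 2.24 ± 0.62 and 14 genes did not pass. Over all genes tested, 0 members of any list rose or fell in GFP-negative cells. S100a8, at 11.9 on control 3, was at 11.02 to 13.2 on the GFP-negative arrays. Myeloid priming genes rose by a median of 0.57 (15 of 18 higher; camera adjusted p = 1.78e-07; adjusted p = 0.11 with an estimated correlation), and 5 rose when adjusted over the list alone, among them Fcgr3 (1.37 ± 0.27, at 6.86 on each of the 3 arrays, a tie of a kind that RMA often gives), Ms4a3 (2.33 ± 0.51) and the transcription factor Irf8 (1.62 ± 0.52). Irf8 differed by 1.07 without control 3 and by 0.81 by the mean of its probe sets. The erythroid list rose by a median of 0.90 (10 of 14 higher; camera adjusted p = 5.79e-05; adjusted p = 0.11 with an estimated correlation), and 6 genes rose when adjusted over the list alone, among them Car1 (2.86 ± 0.49), Slc4a1 (3.33 ± 0.73, or 1.76 by the mean of its probe sets), Ermap (2.60 ± 0.66) and Tfrc (1.45 ± 0.38).

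Immediate early and heat shock genes fell, with a median log2 fold change of -0.62 in GFP-negative cells (18 of 21 lower; camera adjusted p = 5.37e-08; adjusted p = 0.198 with an estimated correlation). Adjusted over the list alone, 5 fell: Zfp36 (-1.17), Nr4a1 (-2.40), Dusp1 (-1.27), Egr1 (-1.48) and Klf6 (-1.17). The study's genes fell, with a median log2 fold change of -2.40 (camera adjusted p = 1.07e-05; adjusted p = 0.11 with an estimated correlation), and 3 of 3 fell when adjusted over the list alone. Procr differed by -2.40 ± 0.37, from 8.04 ± 0.58 in controls to 5.64 ± 0.26 (SD, n = 3 each), the angiopoietin receptor Tek by -2.68 ± 1.05 and the adhesion molecule Esam by -1.31 ± 0.37. This list was chosen on these samples and is not independent evidence.

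Another 11 lists passed camera in GFP-negative cells but lost the call without 1 array. G2/M and mitosis genes rose by a median of 0.43 (24 of 29 higher; camera adjusted p = 5.56e-05; adjusted p = 0.377 with an estimated correlation), but not without control 3 (adjusted p = 0.0789, median 0.11). Prc1, a protein of the mitotic spindle, differed by 1.87 ± 0.64 (1.05 without control 3) and Mki67 by -0.19 ± 0.25. Oxidative phosphorylation genes rose by 0.26 (26 of 38 higher; camera adjusted p = 0.00185; adjusted p = 0.557 with an estimated correlation). Without control 3 they did not pass (adjusted p = 0.583, median 0.0086), and without control 2 the median was 0.42. G1/S and DNA replication genes rose by 0.17 (21 of 29 higher; camera adjusted p = 0.0239; adjusted p = 0.468 with an estimated correlation), with the helicase subunit Mcm2 at 1.28 ± 0.49 (0.76 without control 1). They did not pass without control 3, GFP-negative 2 or GFP-negative 3 (adjusted p = 0.531, 0.057 and 0.136), and the median ranged from 0.04 to 0.31. D-type cyclins and G1 regulators rose by 0.32 (10 of 13 higher; camera adjusted p = 0.0448; adjusted p = 0.214 with an estimated correlation), with Ccnd1, cyclin D1, at 0.79 ± 0.31 (0.48 without GFP-negative 3). They passed only without control 1 or GFP-positive 1 among the 9 fits that each left out 1 array (adjusted p up to 0.169, median down to 0.10 without GFP-negative 1). Ribosome biogenesis genes rose by 0.15 (17 of 25 higher; camera adjusted p = 0.0448; adjusted p = 0.489 with an estimated correlation), with Pes1 at 1.32 ± 0.38 (0.48 by the mean of its probe sets). They did not pass without any 1 of the controls, GFP-negative 2, GFP-negative 3 or GFP-positive 3 (adjusted p from 0.0517 to 0.455), and the median ranged from 0.09 to 0.30.

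Quiescence genes fell, with a median log2 fold change of -0.34 in GFP-negative cells (15 of 21 lower; camera adjusted p = 0.023; adjusted p = 0.214 with an estimated correlation), but not without control 1, control 2 or GFP-negative 2 (adjusted p = 0.06, 0.124 and 0.129, medians -0.20, -0.17 and -0.053). Nr4a1 was the 1 gene that fell when adjusted over the list alone, and Egr1 and Gfi1 differed by -1.48 ± 0.47 and -1.13 ± 0.43 (Gfi1 by -0.65 without control 3). Nr4a1, Egr1, Klf2 and Btg2 are also in the immediate early and heat shock list, so the 2 falls are not separate results. Gfi1 is also in the myeloid priming list, which rose. TNF and NF-kB response genes fell by 0.32 on the log2 scale (10 of 16 lower; camera adjusted p = 0.0394; adjusted p = 0.377 with an estimated correlation), with the NF-kB inhibitor Tnfaip3 at -1.70 ± 0.54 and the chemokine Ccl4 at -1.06 ± 0.36. That list did not pass without control 1, GFP-negative 2, GFP-negative 3, GFP-positive 2 or GFP-positive 3 (adjusted p from 0.0517 to 0.421), and its median ranged from -0.54 to -0.15. Monocyte and macrophage genes rose by 0.95 (9 of 13 higher; camera adjusted p = 0.0234; adjusted p = 0.403 with an estimated correlation), but not without control 2 or GFP-negative 1 (adjusted p = 0.214 and 0.317, medians 0.61 and 0.44), with Ccr2 at 1.52 ± 0.42 (0.53 by the mean of its probe sets). Mast cell and basophil genes rose by 0.61 (8 of 10 higher; camera adjusted p = 0.0234; adjusted p = 0.403 with an estimated correlation), but not without control 1, control 2 or GFP-negative 1 (adjusted p = 0.0756, 0.102 and 0.266, the last with a median of 0.36), with Mcpt8 at 1.14 ± 0.40. B cell genes rose by 0.41 (10 of 13 higher; camera adjusted p = 0.0371; adjusted p = 0.468 with an estimated correlation), but not without control 2 or GFP-negative 1 (adjusted p = 0.587 and 0.862), and the median ranged from 0.042 to 0.76. Genes of multipotent and lymphoid-primed progenitors rose by 0.46 (16 of 23 higher; camera adjusted p = 0.0236; adjusted p = 0.214 with an estimated correlation), but not without control 2, GFP-negative 1 or GFP-negative 2 (adjusted p = 0.19, 0.0794 and 0.106, the last with a median of 0.28). Ighm, the immunoglobulin heavy chain gene in both of these lists, differed by 2.74 ± 0.81 (0.74 by the mean of its probe sets), and Flt3 by -0.03 ± 0.27.

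The other 14 lists did not pass in GFP-negative cells (camera adjusted p from 0.0586 for megakaryocyte and platelet genes, median -0.28, to 0.902). Adjusted over their lists alone, Gng11 fell, and Fabp4 (2.84 ± 0.50, or 1.09 by the mean of its probe sets) and the adhesion genes Pecam1 and Itgal rose. Adhesion and homing genes and ribosomal proteins had medians of -0.073 and -0.019 with means of the opposite sign, 0.058 and 0.022. Of single genes, 0 of 12398 passed limma (smallest adjusted p 0.327), 691 had an unadjusted p under 0.05 (351 higher, 340 lower) against 620 by chance, and in 1415 (11.4%) the groups did not overlap, against 10% by chance. None of the 10 genes with the smallest p passed. Beside Procr, Car1, Dram1 and Fabp4 they were Pklr, the pyruvate kinase of liver and red cells, at 2.34 ± 0.38 and Afap1 at 2.27 ± 0.39. Timp2, a metalloproteinase inhibitor, stood at -2.75 ± 0.47, Tmbim1 at -1.98 ± 0.34, Cdc42bpa at -2.15 ± 0.39 and Bex1 at -1.85 ± 0.34. By the mean of their probe sets Pklr, Afap1, Timp2 and Cdc42bpa differed by 1.09, 0.81, -0.75 and -0.86.

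**Figure D2:**
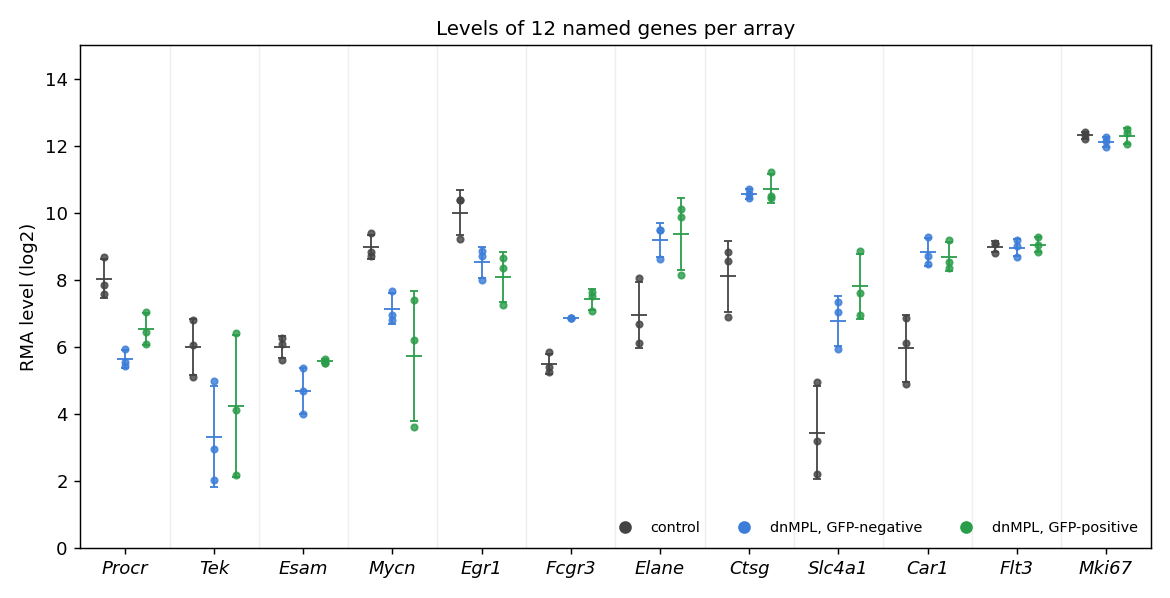
RMA level (y axis, log2) of 12 named genes on each array of control, GFP-negative and GFP-positive LSK cells. Points are arrays and bars the mean ± SD (n = 3); the levels of Procr were 7.57 to 8.69 on controls, 5.43 to 5.93 on GFP-negative and 6.09 to 7.05 on GFP-positive arrays.

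The third comparison set the GFP-positive against the GFP-negative LSK cells of dnMPL mice and asked what differed between cells with and without the GFP marker. No list and no gene passed. HSC identity genes had a median of -0.23 (16 of 24 lower, camera adjusted p = 0.0883, adjusted p = 0.94 with an estimated correlation), which was -0.12 without the filter on dim genes and -0.34 to -0.091 leaving out 1 array. Prdm16 differed by -0.98 ± 0.49 and Mycn by -1.40 ± 0.79, and both were lowest on GFP-positive 2, which stood apart. Mycn stood at 3.60 there, at 6.21 and 7.39 on GFP-positive 1 and 3, and at 6.79 to 7.66 on the GFP-negative arrays. Prdm16 stood at 3.82 there, at 5.12 and 4.75 on GFP-positive 1 and 3, and at 4.66 to 6.36 on the GFP-negative arrays. Granulocyte genes had a median of 0.81 (15 of 16 higher; camera adjusted p = 0.0883) and the erythroid genes one of 0.23 (camera adjusted p = 0.3). The study's genes had a median of 0.89, with 3 of 3 higher in GFP-positive cells (camera adjusted p = 0.0534), and are not independent evidence. They passed with the mean of a gene's probe sets (adjusted p = 0.0237), with median centring (0.0426) and without control 2, control 3, GFP-negative 1 or GFP-positive 1 (from 0.00112 to 0.0423), and did not without any 1 of the other 5 arrays (up to 0.352). Esam and Procr differed by 0.88 ± 0.37 and 0.89 ± 0.37 and Tek by 0.92 ± 1.05, whose difference was -0.17 without GFP-positive 2 and 0.0013 with array weights. Esam differed by 0.54 without GFP-negative 3. Flt3 and Mki67 differed by 0.089 ± 0.27 and 0.18 ± 0.25. The camera adjusted p of the 31 lists lay between 0.0534 and 0.984. At an unadjusted p under 0.05 camera gave 4 lists, and 0 passed with an estimated correlation or with fry. Medians and means differed in sign for G2/M and mitosis (0.056 and -0.013), immediate early (0.051 and -0.0064), interferon response (0.02 and -0.028) and oxidative phosphorylation genes (0.033 and -0.02). Limma called 0 of 12398 genes (smallest adjusted p 1), and 316 had an unadjusted p under 0.05 (159 higher, 157 lower) against 620 by chance. That count was 844 without GFP-positive 3, 203 without GFP-positive 2 and 984 with array weights. Groups did not overlap in 793 genes (6.40%), against 10% by chance. The 10 genes with the smallest p, none of which passed, were led by the ubiquitin ligase Trim41 (1.90 ± 0.33), followed by Rwdd1 (-1.81 ± 0.37), Dpy19l3 (-2.74 ± 0.59), Cd302 (-1.46 ± 0.33), Il15 (-1.45 ± 0.34), Pklr (-1.53 ± 0.38), Txndc15 (1.33 ± 0.33), Pigm (1.29 ± 0.32), Dnajc30 (1.71 ± 0.43) and Gskip (1.44 ± 0.36). With the mean of a gene's probe sets, Trim41, Dpy19l3, Pklr, Pigm and Gskip differed by 0.72, -0.93, -0.53, 0.79 and 0.52. The result moved with single arrays: 6 lists passed without GFP-negative 1, 4 without GFP-positive 2, 2 without control 2 or control 3 and 1 without GFP-positive 1. Without control 3 and GFP-positive 2 together, 5 lists passed, and the granulocyte list was among them (median 0.88, adjusted p = 0.000378). Leaving out 1 array, the granulocyte median ranged from 0.25 without GFP-positive 1 (adjusted p = 0.998) to 1.38 without GFP-negative 1 (adjusted p = 0.000616), and was 0.34 and 0.52 without GFP-negative 3 and 2.

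Both dnMPL fractions were compared with the same 3 control arrays, so part of any likeness between them comes from those arrays. No gene was called in both. At an unadjusted p under 0.05, 299 genes had the same direction in both (158 higher, 141 lower), against a mean of 160 (range 124 to 194) over 100 simulations of unchanged groups and the same controls. The simulations let genes vary independently and gave every array the same spread, so their range is likely too narrow and does not exclude chance. Without GFP-negative 1 the count was 197, without GFP-negative 2 217, without control 2 442 and with array weights 471, and the simulations were not repeated for these fits. Independent sets of these sizes would share 11.6 higher and 10.9 lower genes. The log2 fold changes of the 2 comparisons correlated across genes, which are not independent replicates, with r = 0.66 against 0.50 simulated, and their covariance was 0.219 against 0.135. The 3 controls could not be split into sets of at least 2, so part of the excess may come from the shared controls. Slamf1, a surface marker of HSCs, Cdkn1c, a cell cycle inhibitor of quiescent HSCs, and Vwf, the von Willebrand factor of platelets and platelet-primed HSCs, lay below the filter on dim genes. Their levels were 4.12 ± 0.99, 3.51 ± 0.41 and 3.95 ± 0.41 in controls, 3.51 ± 0.78, 3.15 ± 0.23 and 3.44 ± 0.30 in GFP-negative and 4.35 ± 1.89, 3.40 ± 0.30 and 3.33 ± 0.096 in GFP-positive cells (SD, n = 3 each).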

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

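The test on primary granule genes, the one without control 3 and GFP-positive 2, the gene and list fits of both fractions jointly, and the counts of splits for the single comparisons and for shared genes were chosen only after the results were seen. Of the 64 control probe sets, which no comparison used, 3 were higher on all 6 dnMPL arrays than on all 3 controls and 0 lower, where 0.762 would be higher by chance. The 5′ and middle control probe sets of the mouse transferrin receptor differed by 1.57 ± 0.48 and 1.42 ± 0.27 (SE, log2), and Tfrc is also in the erythroid list. The 3′ probe set of that transcript differed by 1.13 ± 0.46 and did not lie above all controls. Probe sets of the same transcript are not independent, so the count of 3 cannot be weighed against the value by chance. A 5′ probe set of the Cre spike-in, added to every sample, differed by 0.0605 ± 0.0172.

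In both dnMPL fractions HSC identity genes were lower and myeloid, granulocyte and erythroid genes higher. Mature granulocytes carried through the sort have lost primary granule transcripts, so they cannot account for the rise of Mpo, Elane, Prtn3 and Ctsg by 1.58 ± 0.34 (mean log2, 6 dnMPL against 3 control arrays). All 4 are members of the lists to be explained and were known to be higher, so this is not separate evidence. Dilution by cells lacking progenitor transcripts would lower all progenitor genes alike. A list of 10 such genes lay 0.35 ± 0.12 above the HSC identity genes (-0.44 ± 0.14 against -0.79 ± 0.18). That argues against dilution by cells lacking these transcripts as the whole cause, but the SE takes the 6 dnMPL arrays as independent, which the labels do not say. The gap was not taken again with another choice of probe sets, on which the HSC identity gene Mycn depended. Diluting cells that express some of the 10 genes are not covered. The 10 genes also differed among themselves, from -0.95 ± 0.32 (Erg) to 0.13 ± 0.26 (Cd34). Control 3 and GFP-positive 2 alone do not carry the pattern, since 8 of 8 list tests at the preset correlation still passed without them, although the erythroid median in GFP-positive cells was then 0.45 and not 1.10, and 1 of the 8 passed with an estimated correlation on all 9 arrays. Granulocytes and their precursors in the sorted cells stay open. A second list of 11 neutrophil genes, 1 of them also in the lists above, was 1.21 ± 0.45 higher. S100a8 and S100a9 stood at 12.42 and 12.97 on dnMPL arrays against 9.45 and 10.83. A lineage-negative gate is meant to remove mature granulocytes, but whether it removed them all is open. Late granulocyte genes had a mean of 9.24 on control 3 against 6.34 and 5.18 on controls 1 and 2. The primary granule genes were lowest on control 3 (7.89 against 9.25 and 8.66). A shift of LSK cells from stem cells toward committed progenitors, with or without a role of dnMPL, may also account for the pattern. Dilution may account for part of the pattern, since 9 of the 10 progenitor genes were lower (Lmo2 at -0.77 ± 0.14). Added progenitors that express the 10 genes were not separated from such a shift.

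Immediate early and heat shock genes were lower in both dnMPL fractions (-0.71 ± 0.18). A difference in handling before lysis would lower other genes set off by handling, and a second list of 12 such genes differed by -0.18 ± 0.14, and the first list lay at -0.53 ± 0.11 relative to it. That result met the bound set in advance against handling, but 6 of the 12 genes were higher and 6 lower, so their mean near 0 decides nothing (Ppp1r15a stood at -0.92 ± 0.28 and Maff at -1.41 ± 0.67), and this reading was adopted after the result was seen. Handling and a change in signalling cannot be told apart for these genes, because no label gives the order or time of the sorts.

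Splits of 3 against 3 arrays number 10, too few for a share under 0.05. In fits of the 6 arrays compared, GFP-positive against control gave 15 lists (highest other split 9, 1 of 10 as high) and 0 genes (highest other 0, 10 of 10 as high). GFP-negative against control gave 15 lists (highest other 10, 1 of 10 as high) and 0 genes (highest other 0, 10 of 10), and GFP-positive against GFP-negative 2 lists (highest other 8, 5 of 10) and 0 genes (highest other 0, 10 of 10). For genes called in both fractions, 0 in the real grouping, 100 of 100 drawn splits gave as many, the highest other being 1. With both fractions as 6 arrays against 3 controls, 84 of 84 splits gave as many genes as the real 0. The highest other count was 7, with control 1, control 3 and GFP-positive 2 as the 3 arrays, a set that holds both arrays that stood apart. The cause of that count was not tested. A real count of 0 is reached by any split, so neither of these says anything about chance. For lists tested with camera at the preset correlation, 1 of 84 splits, the real one, gave as many as 14 (highest other 12). That excludes chance at the 0.05 level only if the 6 dnMPL arrays came from separate mice, which the labels do not say, and 3 pools against 3 cannot give a share under 0.1. The splits were not repeated with an estimated correlation, with fry or with another filter, so the result holds for this setting only.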

How the results depend on the processing

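The fits without control 3 and GFP-positive 2 together, and those of both fractions jointly, were chosen only after the results were seen. Gene counts were 0 in all 3 comparisons and for shared genes under every alternative run, and 805, 691 and 316 genes had an unadjusted p under 0.05 in limma (1368, 1134 and 984 with array weights, and 680 to 1128, 511 to 863 and 203 to 844 leaving out 1 array). The smallest adjusted p of any named gene was 0.0523 with array weights and 0.123 elsewhere. For GFP-positive against control, 15 lists passed camera, 1 with an estimated correlation and 3 with fry, and leaving out 1 array gave 11 to 16. For GFP-negative against control, 17 passed, 9 with the 60th percentile filter, 0 with an estimated correlation and 2 with fry, and leaving out 1 array gave 10 (without control 2) to 18. For GFP-positive against GFP-negative, 0 passed, 1 with the mean of a gene's probe sets, 1 with median centring and 5 without control 3 and GFP-positive 2, and leaving out 1 array gave 0 to 6 (without GFP-negative 1). The stricter filter tests fewer genes, and an estimated correlation brings fewer degrees of freedom and, where above 0.01, a wider null; the cause of the other changes was not tested. Of 32 list calls against control, 12 held without any 1 array. Over 35 list results and 627 values, 480 kept direction and call, 136 lost the call, 11 gained it and 0 reversed in camera's direction, though 2 medians changed sign: oxidative phosphorylation (-0.049 without control 3) and dendritic cell genes (-0.0042 without control 3 and GFP-positive 2) in GFP-positive against control.

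Of 3183 values of 153 named-gene tests, 17 reversed; the cause was not tested. Mki67 in GFP-positive against control was 0.086 with array weights, 2.97e-05 without control 3 and GFP-positive 2, and -0.11 to 0.12 leaving out 1 array. In GFP-negative against control, the mean of probe sets gave 0.043 for Cd244a and 0.12 for Bcl6 (-0.54 and -0.52 for the brightest), and Flt3 was 0.044 with array weights, 0.0096 without control 3 and GFP-positive 2 and -0.14 to 0.11 leaving out 1 array. Leaving out 1 array, Flt3 ranged from -0.058 to 0.17 in GFP-positive against control and from -0.054 to 0.20 in GFP-positive against GFP-negative. Tek in the latter was -0.17 without control 3 and GFP-positive 2, and -0.17 to 1.95 leaving out 1 array.

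With the number in the titles as a replicate block, 15, 15 and 0 lists and 0 genes passed. Deviations of same-numbered GFP-negative and GFP-positive arrays correlated at 0.0994, -0.043 and -0.066, so they were not treated as pairs, but the labels leave open whether they share mice, and granulocyte levels ran in the same order (2.93, 1.72, 1.22 and 3.53, 2.23, 2.06 above control for arrays 1 to 3). The study's list was not tested at the 60th percentile, which left it under 3 members. Dim genes are limited by signal over background.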

Other observations

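The exact permutation tests of both dnMPL fractions against control were chosen only after the results of the single comparisons were seen. With both fractions pooled as 6 arrays, the dnMPL cells had an erythroid level 1.05 ± 0.095 (SE, log2) above the 3 controls, with 6 of 6 arrays above every control. That level is a mean over a mixed list, in which 9 genes were higher and 5 lower. The HSC identity level lay at -0.79 ± 0.18 with 6 of 6 below. Myeloid priming stood at 0.89 ± 0.18 (6 of 6 above). Immediate early and heat shock genes stood at -0.71 ± 0.18 (6 of 6 below). TNF and NF-kB response genes stood at -0.30 ± 0.15 (6 of 6 below) but did not pass camera (adjusted p = 0.0587) and differed by -0.083 without control 1, which stood at 0.43 against -0.24 and -0.19 on controls 2 and 3. Each of these 5 lists had an exact two-sided p of 0.0119, the smallest that 84 splits can give, and an adjusted p of 0.0738 over 31 lists, so 0 lists passed after adjustment. These p values take the 6 dnMPL arrays as independent, and if arrays of the same number share mice, 3 pools against 3 cannot give an exact p under 0.1. Before adjustment 13 of the 31 lists had an exact p of 0.05 or less, and in 7 lists all 6 dnMPL arrays lay on 1 side of the controls. Among the 13 were the granulocyte list (exact p = 0.0238) and the JAK-STAT target genes, which include Socs and Pim genes downstream of cytokine receptors. The JAK-STAT genes stood at -0.21 ± 0.079 (exact p = 0.0357, adjusted 0.101, 5 of 6 below), and did not pass camera (adjusted p = 0.16). That level, too, is a mean over a mixed list. Its median was -0.036 in GFP-positive cells (8 genes higher, 9 lower) and -0.083 in GFP-negative cells (6 higher, 11 lower). The list shares Fos and Junb with the immediate early and heat shock list. Limma called 0 genes over both fractions, with 959 at an unadjusted p under 0.05, and 3 with array weights.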
